A study of Homo sapiens with 206 samples.

How the data were processed

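RNA of human cell lines was profiled on Affymetrix arrays of 54675 probe sets, each probe set giving 1 signal per array. Per the labels, the cells were grown in RPMI1640 medium with serum, and biotin-labelled total RNA was hybridized. The labels name the cell line and the replicate number of each array and give no tissue of origin, so lines were not grouped by tissue. All 206 arrays and 134 lines were used: 70 lines with 1 array, 56 with 2 and 8 with 3. Each line was a group.

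The deposited values are log2 GCRMA signals, which the submitters' processing notes credit to GCRMA, a background correction, quantile normalization and probe summary for Affymetrix arrays. Its version, and which arrays were normalized together, are not given in the sources used here. The medians of the arrays lay between 2.91 and 3.12 and the highest values between 15.1 and 15.7. No value was missing, and no column was left out.

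Of the 54675 probe sets, 41097 carried a single gene symbol in the platform table, 1801 carried several and 11777 carried none here; the last 2 kinds were left out. Symbols were updated through Entrez identifiers to RefSeq names on GRCh38.p14 for 41043 probe sets, and 54 kept the platform's symbol. This gave 19775 genes, 10523 of them with several probe sets. The probe set with the highest mean over all arrays stood for the gene. Of 6997 genes with several probe sets above the signal limit, 119 had a probe set that correlated negatively with the one chosen. Of the 375 entries of the gene lists, 32 were not analysed here, and neither were 7 of the 40 single genes planned. The 62 control probe sets were used for checks only.

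Genes entered a test when their log2 value was over 5 on at least 2 of the 136 arrays of the 64 lines with 2 or 3 arrays, which left 13332 genes. One linear model per gene, with 1 coefficient per line and 72 residual degrees of freedom, was fitted to the log2 values with limma 3.58.1 in R 4.3.3, with a moderated variance that follows the mean. Each of the 8 lines with 3 arrays, and HLFA with 2, was compared with the unweighted mean of the other 63 coefficients. COLO205 was compared with COLO201, SW620 with SW480 and RKOAS451 with RKO. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 either way. A moderated F-test over all lines asked which genes differed among lines.

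The genes named for a comparison were the called genes with the largest differences, 6 higher and 4 lower against the other lines and 10 each way between 2 lines, and up to 4 called members with the largest differences from each called list. The 27 gene lists were written from textbook knowledge. They were tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the 26 lists that had at least 5 genes tested. Correlations between 12 planned pairs of genes were computed over the line values, 1 per line, with 2-sided permutation tests of 100000 resamples. Lines of shared origin, such as COLO205 and COLO201 or RKO and RKOAS451, counted as separate lines, so these p values may be too small. Where either gene had separate low and high clusters of lines, correlations were computed within clusters, which made 26 relations in the adjustment. Single genes were described by the number of lines at or above a log2 value of 8.

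These choices, the named-gene rule and most other settings tried were fixed before the data were examined. These settings were other probe set choices, filters and variance models, repeated quantile normalization, median centring, array weights, other reference lines, a replicate block, and each array left out in turn. Settings added later are named in the closing part. The test was checked on simulated data, with 200 genes shifted by 1.5, 2 or 3 log2 units in each comparison. Calls of shifted genes numbered 193 to 199 against the other lines, with 0 to 6 false calls, and 173 to 182 between 2 lines, with 2 to 5 false calls. Apart from the shifts, each simulated gene had the same mean in all lines and normal noise of its fitted spread, as the test assumes. Most real genes differed among lines, so these counts do not give the error rate of the real comparisons.

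Nothing in the labels says whether replicate arrays came from separate cultures. The p values therefore measure the spread between arrays, which may be technical only. Each SE given below rests on the spread between replicates pooled over all 64 lines of the fit, not on the arrays of the named line alone. For a gene at background in most lines, such an SE mostly reflects the spread at background. It can be smaller than the spread in the line that expresses the gene. The number of arrays limits the precision, and log2 values between 2 and 3 lie at the background of these arrays, so that differences from such a value are compressed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.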

Results

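Gene expression was measured in 134 human cell lines on 206 arrays, and 64 lines had replicate arrays: 56 with 2 and 8 with 3. The series title names them as cancer cell lines; HLFA is known as a lung fibroblast line. Between 8165 and 9483 of 19775 genes lay above a log2 value of 5 on an array, with a median of 9106. The purpose given for the series is a set of expression profiles, without a named question or control group. The comparisons therefore ask what sets single lines apart from the rest, and what differs between lines with a shared history.

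The arrays fell into 2 technical classes that the labels do not name. The bacterial thr transcript, which is added to RNA as a poly-A control, had a mean log2 signal of 2.61 on 77 arrays of 68 lines and of 13.48 on 129 arrays of 66 lines. No line had arrays in both classes. Of the lines compared, T47D lay in the low class and all others in the high class, so values within a class stand beside the pooled ones.

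Replicate arrays of a line resembled each other closely. The mean Pearson correlation across genes between replicates of a line had a median of 0.991 (SD 0.0236, n = 64 lines), against 0.837 for 9100 pairs of arrays of different lines; genes are not independent replicates in these values. With only the arrays of replicated lines as possible matches, the best match of 133 of 136 arrays (97.8%) was an array of the same line. With all 206 arrays as possible matches this held for 132 of the 136. The exceptions were both JIMT1 arrays, HCT15 replicate 1, closest to DLD1 replicate 2 (0.965), and CX1 replicate 1, closest to HT29 replicate 1 (0.975). HCT15 is also among the lines that DLD1 and HCT8 were set against. Over the genes tested, HCT15 was the closest other replicated line of both, at up to 0.962 for DLD1 and 0.952 for HCT8. The highest value for COLO205 with COLO201 was 0.959. The reference means for DLD1 and HCT8 therefore include a line much like them. Replicates of H596 (mean correlation 0.939) and HCT15 (0.960) resembled each other less than the closest arrays of different lines, RKO and RKOAS451 (0.986). The lowest mean correlation between replicates, 0.814, belonged to JIMT1, a breast carcinoma line. Its arrays disagreed on marker genes: the basal keratin KRT5 read 10.55 and 1.87, and the receptor kinase AXL 10.46 and 2.07. Values of JIMT1 are therefore means of unlike arrays.

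**Figure D1:**
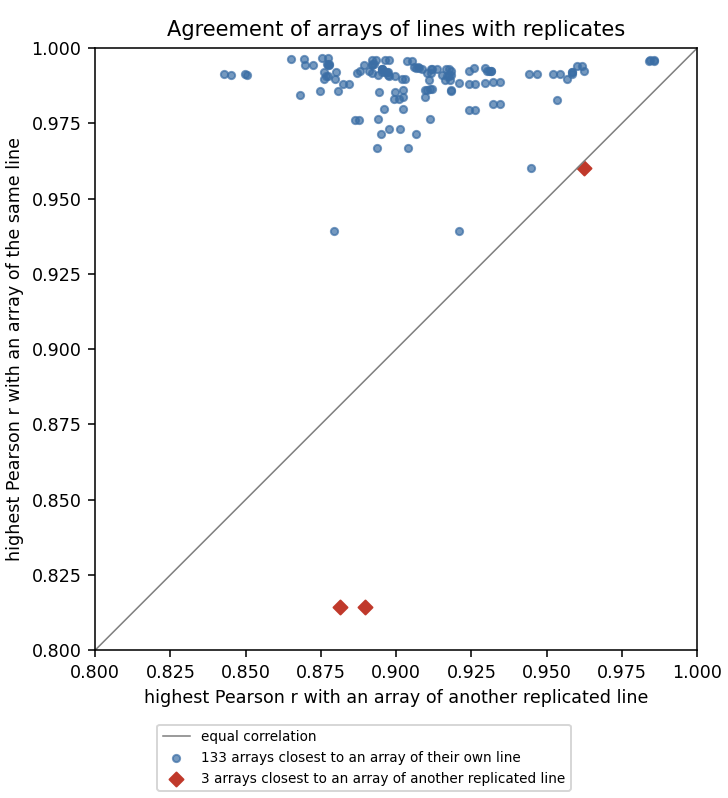
Each point is 1 of the 136 arrays of lines with replicates; axes give its highest Pearson r across genes with an array of another line that has replicates (horizontal) and of its own line (vertical). The 133 blue points lie above the line of equal correlation, and the 3 red diamonds lie below it.

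Nearly every expressed gene differed among lines. With limma's moderated F-test, 13202 of 13332 genes (99%) passed an adjusted p of 0.05 with a range of at least 1 log2 unit. The range of line means had a median of 4.31 log2 units, and 10071 genes ranged over more than 8-fold. The median residual SD between replicates was 0.319.

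Between 2693 and 4154 genes were called when a single line was set against the other 63. Higher genes made up 47.1% (HLFA) to 58.6% (HCT8) of the calls. This balance depended on scaling in 5 lines. After each array was centred on its median it turned in HCT8, in COLO205 (1869 higher, 1812 lower), in COLO201 (1722 and 1750) and in HLFA (2063 and 1985). Repeated quantile normalization turned it in COLO205 (1835 and 1806) and DLD1 (1323 and 1302). The median difference over all genes tested was -0.19 in HLFA, -0.12 in T47D, CACO2 and COLO205 and -0.11 in COLO201, and nearer to 0 in the other lines, so small negative differences in these lines are relative to that shift. For the 76 calls of gene lists, counts adjusted over the list alone equalled those over all genes tested, with the 2 exceptions given beside them. Such differences depend on the lines in the reference. When only the other lines with 3 arrays were the reference, 21 of 348 named genes turned direction and 75 lost their call. CDH1, RAB25, MAL2 and VIM are among them, in a reference where the epithelial list was itself high; CDH1 in LOVO went from 3.24 to -1.03.

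**Figure D2:**
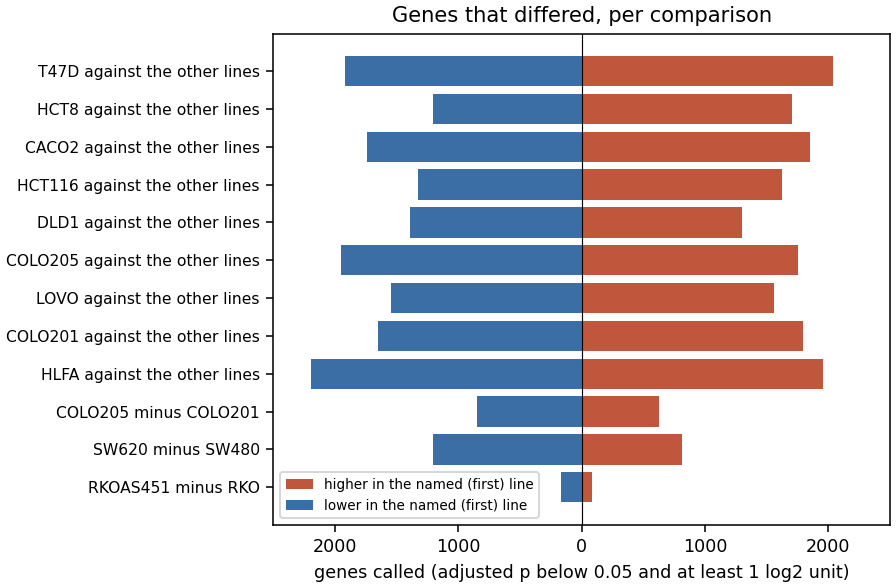
Bars give the number of genes called per comparison (adjusted p under 0.05 and at least 1 log2 unit), higher to the right and lower to the left of 0. HLFA had the most calls, 4154, and RKOAS451 against RKO the fewest, 255.

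T47D, a breast carcinoma line, was set apart from the other lines with replicates by single genes of large difference. SERPINA6, the corticosteroid-binding globulin (probe set 206325_at, chromosome 14), was 12.03 log2 units above the mean of the other lines (SE 0.11, n = 3 arrays), at 13.86 against 1.83. MGP, a matrix calcification inhibitor, was higher by 11.32 (SE 0.69), and PIP, a secreted protein of breast epithelium, by 11.03 (SE 0.41). All 3 genes exceeded every array of the other lines with replicates. Of 11 luminal hormone receptor genes tested, 8 were higher and 0 lower, with a median of 3.98. They included PGR, the progesterone receptor, at 10.86 (SE 0.53), GREB1, an estrogen-induced gene, at 8.46 (SE 0.54) and GATA3, a luminal transcription factor, at 7.56 (SE 0.26). Camera gave this list an adjusted p of 2.74e-06, but adjusted p = 0.158 with an estimated correlation. Lines with 1 array were not in the reference, and the luminal pattern was not particular to T47D. Its mean of the list over all 12 genes, 9.11, lay below MDAMB361 (10.58), BT474 (10.55), ZR751 (10.06), ZR7530 (9.98), HCC1419 (9.72) and MCF7 (9.31), each with 1 array. LDHB, a lactate dehydrogenase subunit, was lower by -10.47 (SE 0.31), CAV1, the caveolae protein, by -8.73 (SE 0.62) and the receptor kinase MET by -8.68 (SE 0.23).

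In T47D 10 of 16 NRF2 target genes, which serve the oxidative stress response, were lower and 1 was higher (median -1.57, adjusted p 0.00143; adjusted p = 0.158 with an estimated correlation). ME1, the malic enzyme, differed by -7.62 (SE 0.15) and AKR1C3, an aldo-keto reductase, by -5.11 (SE 0.36). Among 15 intestinal genes 7 were lower and 1 higher (median -0.85, adjusted p 0.0307; adjusted p = 0.311 with an estimated correlation). The higher one was TFF3, a trefoil peptide that breast lines also make, by 6.25 (SE 0.57). In all, 2040 genes were higher and 1917 lower in T47D. Against lines of its own spike-in class alone, 3755 genes were called, 2850 of them shared with the pooled test. There the NRF2 list had a median of -0.70 (adjusted p 0.201) and AKR1C3 read -0.92. The intestinal list had a median of -0.01 (adjusted p 0.990), so neither list held within the class. Only 8 replicated lines lay in this class, T47D and JIMT1 among them, and no line had arrays in both classes. An effect of the class and a difference in the kind of line therefore cannot be told apart. The intestinal call also ended without the JIMT1 arrays (adjusted p 0.0625). With spike-in level as a covariate 2396 genes were called, but that slope comes from differences within lines and is extended across the gap between classes.

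HCT8, a colorectal carcinoma line, combined intestinal genes with a strong Wnt target pattern. KCNE3, a potassium channel subunit (probe set 227647_at, chromosome 11), was 7.0 log2 units higher than in the other lines (SE 0.32, n = 3 arrays). Of 12 Wnt target genes 8 were higher and 1 lower (median 3.34, adjusted p 3.05e-05; adjusted p = 0.0360 with an estimated correlation). APCDD1, a Wnt inhibitor, was higher by 6.90 (SE 0.41), ASCL2, an intestinal stem cell factor, by 6.73 (SE 0.40) and AXIN2, a feedback regulator, by 5.89 (SE 0.43). Intestinal genes were higher in 7 and lower in 2 of 15 (median 0.19, adjusted p 6.58e-05; adjusted p = 0.0346 with an estimated correlation); TSPAN8, a tetraspanin, was higher by 6.57 (SE 0.16) and VIL1, the microvillus protein villin, by 6.49 (SE 0.24). ELOVL5, a fatty acid elongase, was lower by -8.94 (SE 0.08). BNIP3, a mitochondrial cell death and mitophagy gene, was lower by -6.64 (SE 0.15) and ADM, adrenomedullin, by -4.18 (SE 0.38). They belong to 14 hypoxia and glycolysis genes of which 3 were lower and 1 higher (median -0.22, adjusted p 0.0207; adjusted p = 0.195 with an estimated correlation). Of 10 cholesterol synthesis genes 3 were higher (median 0.87, adjusted p 0.0230; adjusted p = 0.688 with an estimated correlation), with LSS, lanosterol synthase, at 1.82 (SE 0.22); with a replicate block this call ended (adjusted p 0.0560). In total 1707 genes were higher and 1206 lower, or 1397 and 1522 after each array was centred on its median. Within the high spike-in class 2921 genes were called.

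CACO2, a colorectal line that differentiates towards enterocytes in culture, expressed apolipoproteins and plasma proteins. APOA2 (probe set 219466_s_at, chromosome 1) stood 10.92 log2 units above the other lines (SE 0.04, n = 3 arrays), higher than on every array of the other lines with replicates. All 10 liver secreted protein genes tested were higher (median 7.75, adjusted p 1.85e-23; adjusted p = 4.31e-08 with an estimated correlation). FGG, a fibrinogen chain, was higher by 10.02 (SE 0.23), the retinol carrier RBP4 by 9.53 (SE 0.23) and APOA1 by 7.95 (SE 0.08). Among intestinal genes 8 of 15 were higher and 0 lower (median 1.49, adjusted p 8.26e-05; adjusted p = 0.0387 with an estimated correlation), including CDH17, the liver-intestine cadherin, at 7.98 (SE 0.24) and VIL1 at 7.60 (SE 0.24). Cholesterol synthesis genes were higher in 9 of 10 (median 2.13, adjusted p 2.75e-04; adjusted p = 0.519 with an estimated correlation), with SC5D, a sterol desaturase, at 2.60 (SE 0.18). Wnt targets were higher in 8 and lower in 1 of 12 (median 1.65, adjusted p 0.0148; adjusted p = 0.452 with an estimated correlation), led by the receptor TNFRSF19 at 5.24 (SE 0.41); this call ended when all probe sets of a gene were averaged (adjusted p 0.0586). LGALS1, galectin-1, was lower by -9.37 (SE 0.52). The totals were 1847 genes higher and 1742 lower, and 3617 called within the high spike-in class.

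HCT116, a colorectal carcinoma line, had higher p53 targets than the other lines. GTSF1, a germ cell gene (probe set 227711_at, chromosome 12), was higher by 9.23 log2 units (SE 0.17, n = 3 arrays), HBE1, embryonic epsilon-globin, by 8.76 (SE 0.25) and MAGEB2, a cancer testis antigen, by 8.42 (SE 0.23). The cancer testis list was not called, with 4 of 12 members higher and 4 lower (adjusted p 0.860). Of 14 p53 target genes 7 were higher and 0 lower (median 1.02, adjusted p 0.00139; adjusted p = 0.0447 with an estimated correlation). GDF15, a stress-induced cytokine, was higher by 4.68 (SE 0.61), CDKN1A, the cell cycle inhibitor p21, by 2.27 (SE 0.26) and the death receptor FAS by 1.77 (SE 0.34). Amino acid and ER stress genes were higher in 8 of 12 (median 1.44, adjusted p 0.0123; adjusted p = 0.736 with an estimated correlation), with ATF3, a stress transcription factor, at 2.84 (SE 0.74). Intestinal genes were lower in 8 of 15 and higher in 0 (median -1.19, adjusted p 0.00139; adjusted p = 0.118 with an estimated correlation), for example TSPAN8 at -3.39 (SE 0.16). TM4SF1, a membrane protein of the tetraspanin-like family, was lower by -8.24 (SE 0.38). Genes called numbered 1622 higher and 1325 lower, and 2937 within the high spike-in class.

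In DLD1, another colorectal line, OLR1, a receptor for oxidized lipoprotein (probe set 210004_at, chromosome 12), was 8.16 log2 units higher (SE 0.41, n = 3 arrays), and the chemokine CXCL5 was higher by 8.05 (SE 0.41). Wnt targets were higher in 7 and lower in 1 of 12 (median 2.27, adjusted p 1.18e-04; adjusted p = 0.0645 with an estimated correlation), among them LGR5, the stem cell receptor, at 6.43 (SE 0.37) and AXIN2 at 5.96 (SE 0.43). Intestinal genes were higher in 6 and lower in 3 of 15; the median was -0.08 while the mean was 1.5, and camera gave the higher direction (adjusted p 0.0185; adjusted p = 0.264 with an estimated correlation). KRT20, an intestinal keratin, was higher by 6.75 (SE 0.27) and CDX2, an intestinal homeobox factor, by 4.85 (SE 0.26). Amino acid and ER stress genes were higher in 7 of 12 (median 1.55, adjusted p 0.00663; adjusted p = 0.442 with an estimated correlation), led by CHAC1, a glutathione-degrading enzyme, at 3.48 (SE 0.67). Cholesterol synthesis genes were higher in 5 of 10 (median 0.93, adjusted p 0.0174; adjusted p = 0.555 with an estimated correlation), with HMGCS1 at 1.87 (SE 0.35). INSIG1, at 1.33 (SE 0.51), lost its call without replicate 3 (0.85) or replicate 1 (1.26).

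Lower in DLD1 were ELOVL5 by -8.95 (SE 0.08) and LGALS1 by -7.95 (SE 0.52). NRF2 targets were lower in 6 and higher in 1 of 16 (median -0.65, adjusted p 0.0499; adjusted p = 0.432 with an estimated correlation), with AKR1C3 at -4.96 (SE 0.36). Ovarian and Mullerian genes were lower in 3 of 6 (median -1.17, adjusted p 0.0228; adjusted p = 0.0645 with an estimated correlation), led by MECOM at -2.63 (SE 0.27). When all probe sets of a gene were averaged, the intestinal (adjusted p 0.0653), NRF2 (0.0541) and ovarian (0.0541) calls ended; with a replicate block the NRF2 (0.0576) and cholesterol (0.0547) calls did, and within the high spike-in class the ovarian call did (0.0522). In DLD1 1300 genes were higher and 1393 lower, and 2678 were called within the class.

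COLO205, a colorectal line, had the highest median of the intestinal list among the lines compared. PLA2G2A, a secreted phospholipase (probe set 203649_s_at, chromosome 1), was higher by 11.67 log2 units (SE 0.36, n = 3 arrays). It exceeded every array of the other lines with replicates. STYXL2, a pseudophosphatase, was higher by 10.53 (SE 0.05), LYZ, lysozyme, by 10.09 (SE 0.21) and LCK, a lymphocyte kinase, by 9.77 (SE 0.34). Intestinal genes were higher in 8 and lower in 2 of 15 (median 5.99, adjusted p 5.19e-07; adjusted p = 0.00991 with an estimated correlation), with LGALS4, galectin-4, at 9.25 (SE 0.13) and MUC13, a membrane mucin, at 7.45 (SE 0.23). Wnt targets were higher in 9 and lower in 1 of 12 (median 3.46, adjusted p 1.55e-05; adjusted p = 0.0359 with an estimated correlation), with ASCL2 at 5.72 (SE 0.40). Of 12 TRAIL receptor and O-glycosylation genes 8 were higher and 1 lower (median 1.09, adjusted p 0.00153; adjusted p = 0.0728 with an estimated correlation). FUT3, a fucosyltransferase, was higher by 4.54 (SE 0.31) and GALNT3, which starts O-glycans, by 4.25 (SE 0.27). HMGN3, a nucleosome-binding protein, was lower by -9.47 (SE 0.11) and PFN2, profilin-2, by -9.24 (SE 0.16).

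Stress, sterol, antigen presentation and ERBB2 region lists were called in COLO205 only with the preset correlation. Amino acid and ER stress genes were higher in 8 of 12 (median 1.35, adjusted p 0.00347; adjusted p = 0.410 with an estimated correlation), with TRIB3, a stress pseudokinase, at 2.92 (SE 0.41). Cholesterol synthesis genes were higher in 5 of 10 (median 1.03, adjusted p 0.0111; adjusted p = 0.466 with an estimated correlation), with STARD4, a sterol carrier, at 3.02 (SE 0.37). Class I antigen presentation genes were higher in 5 and lower in 1 of 11 (median 0.88, adjusted p 0.0350; adjusted p = 0.466 with an estimated correlation), with PSMB8, an immunoproteasome subunit, at 2.30 (SE 0.43); within the high spike-in class this call ended (adjusted p 0.0522). The ERBB2 region had 4 of 8 genes higher (median 0.94, adjusted p 0.0473; adjusted p = 0.159 with an estimated correlation), with ERBB2 at 1.30 (SE 0.22). Called genes were 1756 higher and 1952 lower, and 3726 within the class.

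LOVO, a colorectal line, had the highest LGR5 of all 134 lines and high intestinal genes. CALB1, a calcium-binding protein (probe set 205626_s_at, chromosome 8), was higher by 9.81 log2 units (SE 0.19, n = 3 arrays), LGR5 by 9.23 (SE 0.37) and CCND2, cyclin D2, by 8.45 (SE 0.47). Intestinal genes were higher in 9 and lower in 1 of 15 (median 2.41, adjusted p 3.28e-08; adjusted p = 0.00578 with an estimated correlation), with CDH17 at 8.26 (SE 0.24) and CEACAM5, carcinoembryonic antigen, at 6.95 (SE 0.36). Basal and squamous genes were higher in 5 and lower in 2 of 10 (median 0.73, adjusted p 0.0275; adjusted p = 0.0712 with an estimated correlation). SERPINB5, maspin, was higher by 6.69 (SE 0.49) and DSC3, a desmosomal cadherin, by 5.35 (SE 0.14), while S100A2 was lower by -3.54 (SE 0.53). LGALS1 was lower by -9.60 (SE 0.52), and MAGED1 by -7.68 (SE 0.21). The test called 1562 genes higher and 1543 lower, and 3072 within the high spike-in class.

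COLO201, a colorectal line, had high Wnt targets and a raised ERBB2 region. STYXL2 (probe set 232252_at, chromosome 1) was higher by 10.78 log2 units (SE 0.05, n = 3 arrays), FGF19, an enteric hormone, by 10.20 (SE 0.38) and PCK1, the gluconeogenic carboxykinase, by 9.45 (SE 0.34). Wnt targets were higher in 9 and lower in 1 of 12 (median 4.35, adjusted p 1.37e-07; adjusted p = 0.0146 with an estimated correlation), with ASCL2 at 7.06 (SE 0.40) and LEF1, a Wnt transcription factor, at 5.67 (SE 0.36). In the ERBB2 region 4 of 8 genes were higher and 0 lower (median 1.15, adjusted p 0.00259; adjusted p = 0.0244 with an estimated correlation): the adaptor GRB7 by 3.20 (SE 0.24) and the receptor ERBB2 by 2.49 (SE 0.22). Intestinal genes were higher in 7 and lower in 3 of 15, with a median of -0.14 and a mean of 1.89, and camera gave the higher direction (adjusted p 0.00297; adjusted p = 0.143 with an estimated correlation). Amino acid and ER stress genes were higher in 7 and lower in 1 of 12 (median 1.21, adjusted p 0.0330; adjusted p = 0.567 with an estimated correlation); HERPUD1, an ER quality control gene, was higher by 2.07 (SE 0.25) and ATF3 lower by -2.88 (SE 0.74). HMGN3 was lower by -9.48 (SE 0.11). Of 3441 genes called 1790 were higher, and 3451 were called within the high spike-in class.

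Epithelial junction and keratin genes were higher in each of these 8 lines, in 13 (LOVO) to 17 (CACO2, COLO205 and COLO201) of 18 genes. The list medians ran from 2.21 in LOVO, where 1 gene was lower, to 3.43 in T47D, and the adjusted p values from 1.72e-12 in COLO201 to 1.60e-07 in LOVO. With an estimated correlation the adjusted p values were 0.00579 to 0.0447, but in LOVO adjusted p = 0.0582 with an estimated correlation. PRSS8, an epithelial channel-activating protease, was higher by 4.70 (SE 0.29) in HCT8 and by 5.74 (SE 0.29) in CACO2, and ESRP1, an epithelial splicing factor, by 4.76 (SE 0.33) in HCT116, 5.11 (SE 0.33) in COLO205 and 5.30 (SE 0.33) in COLO201. Mesenchymal genes were lower in 13 to 15 of 17 in 7 of the lines, with medians from -2.85 in T47D to -2.10 in DLD1. FN1, fibronectin, was lower by -7.16 (SE 0.64) in HCT8 and -7.23 (SE 0.64) in LOVO. Other members were higher: S100A4 by 5.17 (SE 0.31) in COLO201. The mesenchymal call held with an estimated correlation in HCT8 (adjusted p = 0.0296 with an estimated correlation) and DLD1 (0.0379), and not in T47D (0.0592), HCT116 (0.168), COLO205 (0.0768), LOVO (0.0582) or COLO201 (0.248). In CACO2 it was not called (10 lower, 3 higher, adjusted p 0.0585).

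Fibroblast matrix genes were lower in 6 (HCT116) to 11 (COLO201) of 18 in the same 7 lines, with medians from -1.26 in COLO201 to -0.71 in HCT116. COL5A2, a fibrillar collagen, was lower by -2.93 (SE 0.36) in HCT116 and by -2.99 (SE 0.36) in COLO201, while COL6A2 was higher by 3.63 (SE 0.51) in HCT116. This list kept its call with an estimated correlation in HCT8 (adjusted p = 0.0299 with an estimated correlation), DLD1 (0.00579), COLO205 (0.0359) and COLO201 (0.0198), and lost it in T47D (0.158), HCT116 (0.118) and LOVO (0.0582). In CACO2 it was not called (6 higher, 3 lower, adjusted p 0.427). Cancer testis genes were lower in 8 of 12 in HCT8, CACO2, DLD1, COLO205 and COLO201 and in 7 in LOVO, where the helicase DDX43 was higher by 3.88 (SE 0.14); in T47D the list was not called (7 lower, 1 higher, adjusted p 0.0615). PRAME differed by -3.76 (SE 0.14) in DLD1 to -3.81 (SE 0.14) in CACO2. With an estimated correlation the adjusted p values were 0.00588 to 0.0359, except in LOVO, where adjusted p = 0.139 with an estimated correlation. Mesenchymal genes in HCT8 numbered 14 lower over all genes tested and 15 when adjusted over the list alone.

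HLFA had the profile of a fibroblast culture. COL6A3, a collagen VI chain (probe set 201438_at, chromosome 2), was 11.74 log2 units higher than in the other lines (SE 0.08, n = 2 arrays), GREM1, a BMP antagonist, 11.09 (SE 0.19) and the collagen COL1A2 10.57 (SE 0.19). Fibroblast matrix genes were higher in 17 of 18 (median 7.49, adjusted p 5.25e-33; adjusted p = 6.69e-12 with an estimated correlation), and DCN, the proteoglycan decorin, was higher by 9.94 (SE 0.07). Mesenchymal genes were higher in 16 of 17 (median 5.48, adjusted p 3.12e-13; adjusted p = 3.89e-04 with an estimated correlation), with LOX, the collagen crosslinking oxidase, at 9.70 (SE 0.48). Epithelial junction and keratin genes were lower in 17 of 18 (median -4.28, adjusted p 1.18e-13; adjusted p = 0.00183 with an estimated correlation), KRT18 by -11.01 (SE 0.25) and EPCAM by -7.18 (SE 0.34). Of 14 p53 targets 9 were higher (median 1.43, adjusted p 1.03e-04; adjusted p = 0.00476 with an estimated correlation), including FAS at 3.99 (SE 0.42) and CDKN1A at 3.90 (SE 0.32).

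Class I antigen presentation genes were higher in 7 of 11 in HLFA (median 1.21, adjusted p 0.0168; adjusted p = 0.554 with an estimated correlation), with HLA-B at 1.54 (SE 0.25); PSMB9, at 2.41 (SE 0.69), read 2.21 without replicate 2 and was then not called. Intestinal genes were lower in 7 of 15 (median -1.19, adjusted p 0.0347; adjusted p = 0.328 with an estimated correlation) and basal and squamous genes in 5 of 10 (median -1.31, adjusted p 0.0347; adjusted p = 0.0988 with an estimated correlation), the integrin ITGB4 by -4.89 (SE 0.47). Both calls ended when all probe sets of a gene were averaged (adjusted p 0.0572 and 0.0608). Cancer testis genes were lower in 7 of 12 (median -1.29, adjusted p 0.00898; adjusted p = 0.0988 with an estimated correlation), with PRAME at -3.33 (SE 0.17). HLFA had 1957 genes higher and 2197 lower, and 4178 called within the high spike-in class.

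**Figure D3:**
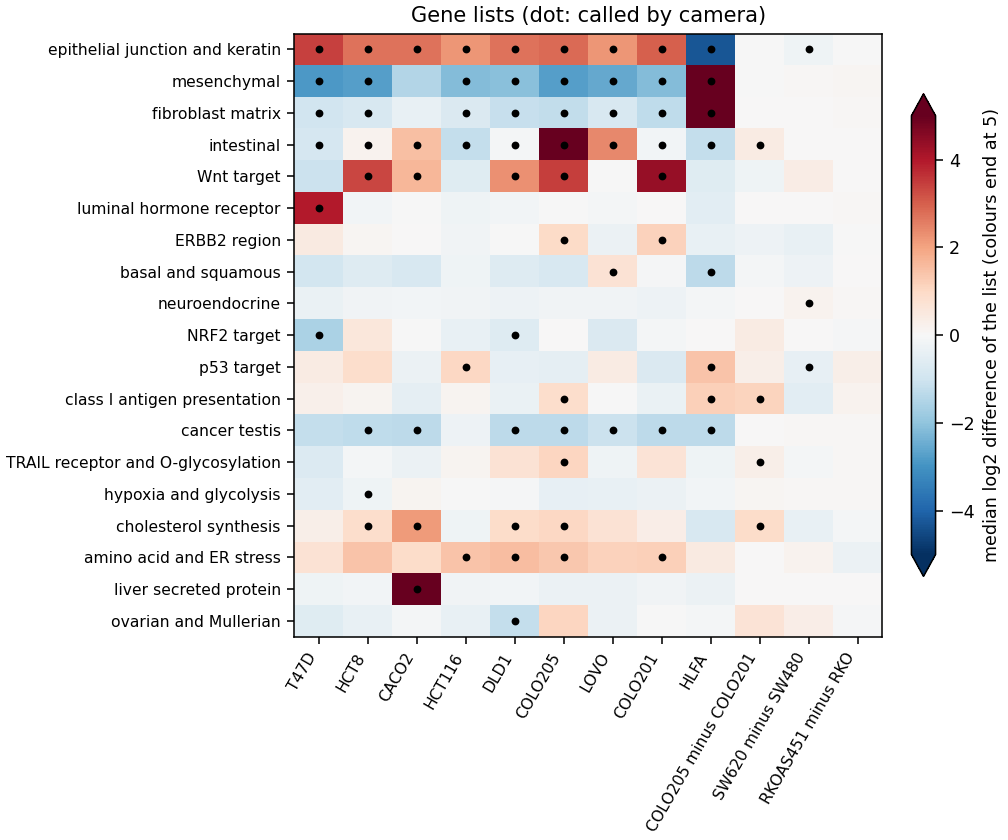
Colours give the median log2 difference of each gene list (vertical) in each comparison (horizontal), with the colour scale ending at 5 either way; dots mark lists called by camera at the preset correlation. The fibroblast matrix list reached 7.49 in HLFA, and the liver secreted protein list 7.75 in CACO2.

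COLO205 and COLO201, lines of shared origin, differed in 1478 genes. CDH17 (probe set 209847_at, chromosome 8) was 8.38 log2 units higher in COLO205 (SE 0.34, n = 3 arrays against 3), at 10.46 against 2.07. BAAT, a bile acid conjugating enzyme, was higher by 7.56 (SE 0.10), CASP1, the inflammasome protease, by 7.31 (SE 0.32), SPINK1, a secreted trypsin inhibitor, by 7.22 (SE 0.27) and FABP1, the liver fatty acid binding protein, by 6.12 (SE 0.23). Intestinal genes were higher in COLO205 in 6 and lower in 1 of 15 (median 0.40, adjusted p 7.52e-07; adjusted p = 0.0176 with an estimated correlation), and the one lower was KRT20, by -4.36 (SE 0.38). Higher in COLO201 were APOBEC3G, an antiviral deaminase (-7.93, SE 0.44), CAV1 (-7.42, SE 0.87), FN1 (-7.33, SE 0.90) and GZMA, a lymphocyte protease (-6.91, SE 0.14). Class I antigen presentation genes were higher in COLO205 in 4 of 11, or 6 when adjusted over the list alone (median 1.11, adjusted p 5.64e-05; adjusted p = 0.342 with an estimated correlation), with HLA-B at 1.33 (SE 0.29). Of 12 TRAIL receptor and O-glycosylation genes 2 were higher (median 0.29, adjusted p 0.0138; adjusted p = 0.342 with an estimated correlation), FUT6 by 2.51 (SE 0.12) and TNFRSF10C, a decoy receptor, by 1.30 (SE 0.19); TNFRSF10C read 0.82 without COLO205 replicate 2. Cholesterol synthesis genes were higher in 2 of 10 (median 0.92, adjusted p 0.0105; adjusted p = 0.693 with an estimated correlation): STARD4 by 1.78 (SE 0.51), which read 1.39 and lost its call without COLO201 replicate 1, and LSS by 1.02 (SE 0.31), which lost its call without that array (0.67) or without COLO205 replicate 3 (0.83). Replicate 3 of such lines had higher INSIG1 and MVD, members of the same list, by 1.19 and 1.26. The test called 629 genes higher in COLO205 and 849 lower, but 759 and 735 after each array was centred on its median, and 719 and 751 after repeated quantile normalization; both lines lie in the high spike-in class.

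SW620 and SW480, colorectal lines known to come from a metastasis and a primary tumour, were compared for what differs along such a history. In SW620 MFNG, a Notch glycosyltransferase (probe set 204153_s_at, chromosome 22), was higher by 8.65 log2 units (SE 0.16, n = 2 arrays against 2), MME, a membrane metallopeptidase, by 7.80 (SE 0.55), SOX2, a stem cell transcription factor, by 7.52 (SE 0.54) and LGR5 by 7.19 (SE 0.63). KRT5 was lower by -11.29 (SE 0.76), CST1, a cystatin, by -9.98 (SE 1.12) and CCND2 by -9.03 (SE 0.81). Epithelial junction and keratin genes were lower in 4 and higher in 1 of 18 (median -0.21, adjusted p 0.0377; adjusted p = 0.741 with an estimated correlation): MAL2, a transcytosis protein, by -8.39 (SE 0.36) and CLDN7, a tight junction claudin, by -7.67 (SE 0.41). The higher one, ELF3, at 1.55 (SE 0.53), lost its call without either SW480 array (1.56 and 1.55) or without SW620 replicate 2 (1.26). Neuroendocrine genes were higher in 4 and lower in 1 of 10 (median 0.16, adjusted p 0.0377; adjusted p = 0.263 with an estimated correlation), with the secretory granule proteins CHGB at 6.34 (SE 0.72) and SCG2 at 5.44 (SE 0.80). Of 14 p53 targets 4 were lower (median -0.41, adjusted p 0.0377; adjusted p = 0.263 with an estimated correlation), FAS by -5.54 (SE 0.58) and CDKN1A by -3.51 (SE 0.44). In SW620 811 genes were higher and 1202 lower, or 1011 and 1061 after repeated quantile normalization and 934 and 1101 after median centring. With only the arrays of these 2 lines in the fit, 1239 genes were called, 1187 of them shared with the larger fit.

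RKOAS451, a derivative of the colorectal line RKO, differed from it in far fewer genes. SFTA1P, a pseudogene transcript (probe set 243818_at, chromosome 10), was higher by 7.13 log2 units (SE 0.43, n = 2 arrays against 2), MYOF, a membrane repair protein, by 6.17 (SE 0.55), LAMA1, a laminin chain, by 5.92 (SE 0.18) and ANXA1, a phospholipid-binding protein, by 4.88 (SE 0.62). STC1, a secreted glycoprotein hormone, was lower by -10.25 (SE 0.90), EFNB2, the ligand ephrin-B2, by -9.17 (SE 0.63), CD274, the immune checkpoint ligand PD-L1, by -9.04 (SE 1.09) and IL13RA2, an interleukin receptor chain, by -8.16 (SE 0.79). In RKO CD274 read 11.05 and in RKOAS451 2.01. In total 87 genes were higher and 168 lower, 65 of them by more than 8-fold. Camera called 0 of 26 lists and found 1 at an unadjusted p under 0.05; the p53 targets came closest (median 0.29, adjusted p 0.369). The count depends on single arrays and on the fit: it was 169 without replicate 1 of either line, and 408 with only the 4 arrays of the pair (213 shared), while array weights kept all 255 and added 267.

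Epithelial and mesenchymal markers divided the 134 lines into groups. Values of CDH1, E-cadherin, were separated by a valley at 6.95 and those of VIM, the filament protein vimentin, by one at 8.27. High CDH1 with low VIM was found in 46 lines, low CDH1 with high VIM in 43, both high in 39 and both low in 6. Among the lines with both high, the markers were inversely related (r = -0.574, rho = -0.582, n = 39, permutation p 1.8e-04, adjusted p 7.8e-04); r was -0.573 without the 2 farthest lines, -0.498 in the low spike-in class and -0.663 in the high class. No such relation passed the threshold in the other groups: r was 0.086 (n = 43, adjusted p 0.806) with low CDH1 and high VIM, 0.051 (n = 46, adjusted p 0.806) with high CDH1 and low VIM, and 0.657 in the 6 lines with both low. CDH1 and ESRP1 were both above their valleys in 77 lines and both below in 38. ESRP1 alone lay above in 11 lines and CDH1 alone in 8. In those 8 lines r was 0.875 (n = 8, permutation p 0.00338, adjusted p 0.01255) and rho 0.762 (adjusted p 0.0958). Without the 2 farthest of them r was 0.702. No relation of CDH1 and ESRP1 passed the threshold in the other groups. ZEB1, a repressor of CDH1, lay above its valley in 41 of the lines with low CDH1 and in 18 of those with high CDH1.

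**Figure D4:**
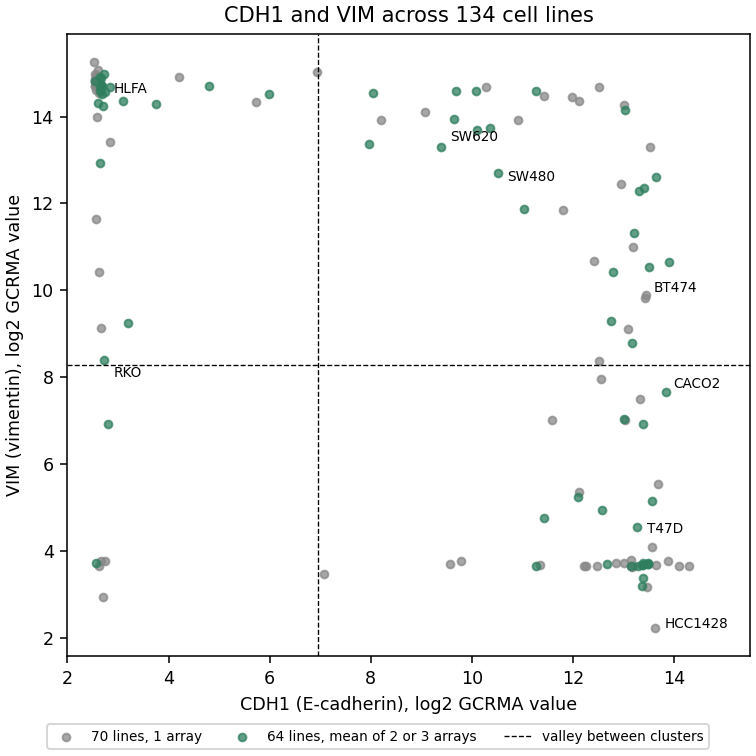
Each point is 1 of 134 lines, placed by its log2 value of CDH1 (horizontal) and VIM (vertical); grey lines have 1 array and green ones are means of 2 or 3. Dashed lines mark the valleys at 6.95 and 8.27; HLFA lies at top left and T47D at lower right.

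Other pairs of genes had been chosen for shared pathways or neighbouring positions. TAP1 and PSMB9, of peptide supply to class I molecules, correlated across all lines (r = 0.828, rho = 0.818, n = 134, permutation p 1e-05, the smallest that the resamples can give, adjusted p 8.67e-05); r was 0.823 and 0.837 in the low and high spike-in classes. CDKN2A, a cell cycle inhibitor gene, correlated with its neighbour MTAP (r = 0.470, rho = 0.417, n = 134, permutation p 1e-05, adjusted p 8.67e-05; 0.560 and 0.477 within classes). NQO1 and GCLM, both NRF2 targets, had r = 0.403 and rho = 0.469 (n = 134, permutation p 2e-05, adjusted p 1.3e-04; 0.312 and 0.511 within classes). Among the 122 lines above the ERBB2 valley, ERBB2 and its neighbour GRB7 had r = 0.855 and rho = 0.753 (n = 122, permutation p 1e-05, adjusted p 8.67e-05; 0.915 and 0.649 within classes); in the 12 lines below it r was -0.108 (n = 12, adjusted p 0.806). Without the 2 farthest lines r was 0.827, 0.457, 0.404 and 0.836 for these pairs. GALNT3 and FUT3 had r = 0.414 and rho = 0.424 in the 88 lines above the GALNT3 valley (n = 88, permutation p 1.5e-04, adjusted p 7.8e-04; 0.402 without the 2 farthest lines; 0.336 and 0.461 within classes). In the 46 lines below that valley rho was 0.428 (permutation p 0.00347, adjusted p 0.0113), but r was 0.234 (permutation p 0.104, adjusted p 0.194). CDX2 and CDH17 had rho = 0.724 in the 113 lines with low CDH17 (permutation p 1e-05, adjusted p 5.2e-05). There r was only 0.062 (permutation p 0.0726, adjusted p 0.145), and -0.019 without the 2 farthest lines. CDX2 lay below 5 in 119 of all 134 lines, with a median of 2.42. This rho therefore mostly ranks CDX2 values near background and does not show joint expression. In the 21 lines with high CDH17 r was 0.180 (permutation p 0.432, adjusted p 0.624). In the 10 lines with high MLANA, a melanocyte antigen, r with MITF was 0.788 (rho = 0.661, n = 10, permutation p 0.0145 and 0.0433, adjusted p 0.0470 and 0.1003), but 0.453 without the 2 farthest lines, on which the relation therefore rests. In the 124 lines with low MLANA r was -0.213 and rho -0.203 (n = 124, permutation p 0.0174 and 0.0242, adjusted p 0.0503 and 0.0698). MYC and CCND1 in the 125 lines with high CCND1 had r = -0.036 and rho = -0.113 (n = 125, permutation p 0.691 and 0.211, adjusted p 0.806 and 0.348); r went opposite ways in the low (0.202) and high (-0.274) spike-in classes.

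Receptors and oncogenes reached extreme levels in few lines. ERBB2 was at or above 8 in 96 of 134 lines, with AU565 (14.56), HCC1954 (14.55) and EFM192A (14.54) at the top. MET was highest in EBC1 (15.09) and H1993 (14.99), EGFR in H1838 (14.09) and FGFR2 in CACO2 (11.93), which were at or above 8 in 111, 83 and 24 lines. MYC lay at or above 8 in 128 lines, highest in COLO320DM (15.12) and lowest in VMRCLCD (2.47), the line with the highest MYCN (14.63). CCNE1, cyclin E1, peaked in HCC1569 (12.61), FUOV1 (11.72) and OVCAR3 (11.23). Among tumour suppressor genes, RB1 lay under 5 in 5 lines, SMAD4 in 9, SMARCA4 in 4 (lowest in A427, 3.46) and CDKN2A in 37. These levels came from 1 probe set per gene. With all probe sets averaged, 12 lines instead of 96 reached 8 for ERBB2, 0 instead of 83 for EGFR and 71 instead of 111 for MET, because probe sets with little signal enter the mean; with 9 as the limit ERBB2 had 61.

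Several lineage factors marked small sets of lines. MS4A1, the B cell antigen CD20, read 9.97 to 14.43 in 6 lines and below 5 in the other 128. PAX8, a factor of Mullerian and renal epithelium, reached 8 in OVCAR3 (12.01), FUOV1 (11.80), SKOV3 (10.67), CAL51 (10.02) and EFO21 (9.17). NKX2-1, a lung and thyroid factor, reached 8 in 13 lines, highest in RERFLCAD1 (12.15), and CDX2 in 8, highest in COLO320HSR (12.95). MITF, the melanocyte factor, was highest in G361 (13.84) and SKMEL28 (13.76), but it reached 8 in 58 of 134 lines. CD274 reached 8 in 15 lines, with CAL851 at 11.96, and ABCB1, a drug efflux pump, in 6, with COLO320DM at 11.17. For ESR1, the estrogen receptor, no line passed 4.21 on the probe set chosen by the highest mean, so these values say nothing of receptor expression. The pair ESR1 and GATA3 (r = -0.169, rho = -0.098, n = 134, permutation p 0.0508 and 0.258, adjusted p 0.110 and 0.394; -0.166 without the 2 farthest lines; -0.103 and 0.042 within classes) is limited in the same way.

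**Figure D5:**
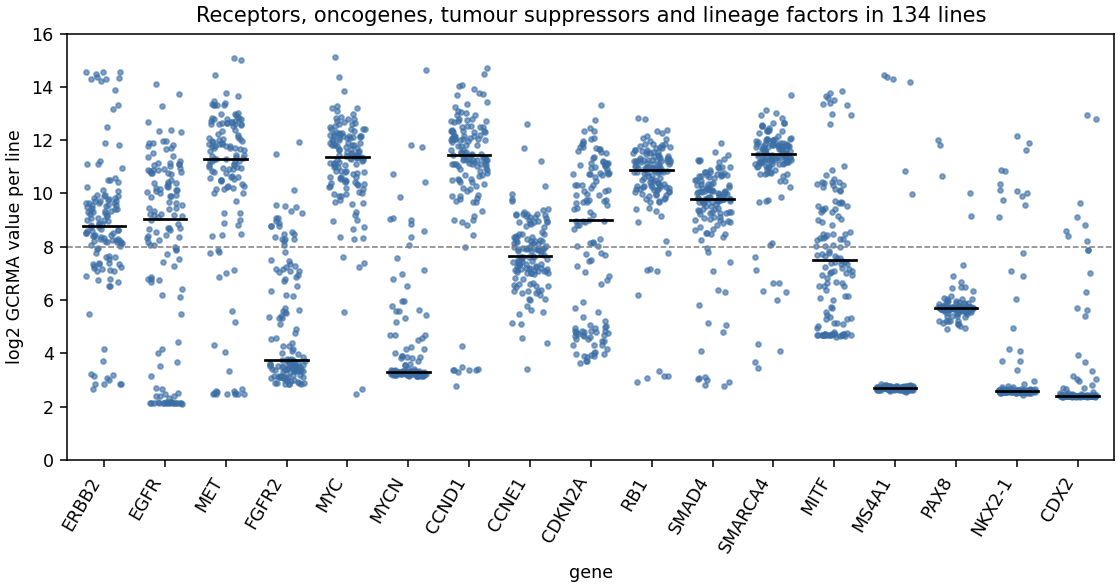
Each point is the log2 value of a gene (horizontal) in 1 of 134 lines, bars mark medians over lines, and the dashed line marks a value of 8. MS4A1 reached 8 in 6 lines and PAX8 in 5, while MYC did in 128.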

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

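The tests of spike-in and 18S signals were fixed before their results were seen, except the fits with spike-in level or 18S signal as a covariate and the comparisons within spike-in classes. No biological explanation was tested for these signals, since the design names none.

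The bacterial thr control probe sets, which no comparison used, split the arrays into classes 10.87 log2 units apart, with means of 2.61 on 77 arrays and 13.48 on 129 arrays. Among the 7 lines with 3 arrays in the high class, replicate 3 read 13.54 to 13.78, against 11.72 to 12.67 for replicate 1 and 11.28 to 12.56 for replicate 2. Within these lines 632 of 13332 human genes (4.74%) passed an adjusted p of 0.05 in limma for replicate 3 against the other two, whatever their size, and 0 genes did for replicate 1 or replicate 2 (674 and 641 at an unadjusted p under 0.05); 44 of the 632 also differed over 2-fold, as a called gene must. Replicate 3 lay near the median of the high class, 13.655, so replicates 1 and 2 of these lines stand apart from most of the class. A separate preparation of these arrays or of the third ones may therefore have shifted human genes too. Comparisons within the high class do not remove such a difference. The labels give no preparation or date. Of the 632 genes 188 were higher in replicate 3 and the rest lower. Among 2-fold shifts PTPRO (1.97), MVD (1.26) and INSIG1 (1.19) were higher, and ID1 (-1.60) and CBX5 (-1.38) lower. Small differences in cholesterol genes between lines with 3 arrays and others are limited by this shift.

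The probe set for the 5-prime end of 18S ribosomal RNA differed by up to 7.33 log2 units between 2 arrays of the same line, and by over 2 in 32 lines; the median difference between arrays of a line was 1.97. Degradation would link it to the 3-prime excess of actin. Over the 56 lines with 2 arrays r was 0.138 (permutation p 0.34, rho -0.121, 95% bootstrap interval -0.337 to 0.36). It was 0.143 without the 2 lines farthest from the median 18S difference. The wide interval leaves degradation open. On SKMES1 replicate 2 the actin excess was 2.90, the highest of all arrays, against 0.66 on replicate 1. Its 18S signal was 9.14 against 3.33, so this line may weigh on r. A labelling difference that moves gene values was argued against: with 18S signal as a covariate within lines 0 of 13332 genes (0%) passed an adjusted p of 0.05 in limma, with 556 at an unadjusted p under 0.05. Carry-over of ribosomal RNA into labelling remained untested.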

How the results depend on the processing

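The settings without JIMT1 or SKMES1, with spike-in level or 18S signal as a covariate, within a spike-in class, and with a replicate block on 2 lines alone were chosen after the data were seen. Of 250 counts and replicate correlations under other settings, 244 kept their size, counts within 1.5-fold; the other 6 follow, and the cause was not tested unless given. Array weights gave 5.2e+02 genes for RKOAS451 against RKO, the 255 called before and 267 more. With only the arrays of the 2 lines that comparison called 408 (213 shared) and SW620 against SW480 1239 (1187 shared). The count thus rose for RKOAS451 and fell for SW620. Fewer arrays estimate the spread there, but the cause was not tested. Spike-in level as a covariate gave 2396 for T47D (1419 shared). No line had arrays in both classes, so that slope comes from differences within lines and is extended across the gap between classes. The count therefore does not show how the T47D calls depend on the class. Leaving out single arrays gave 169 to 174 for RKOAS451 against RKO, lowest without replicate 1 of either line, with the lone array assumed to vary like other lines; ranges were 1659 to 1869 for SW620 against SW480 and 1342 to 1521 for COLO205 against COLO201.

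Named genes kept direction and call in 7909 of 8075 cases and lost the call in 144. They reversed in 22, and 21 of these arose with only the other 3-array lines as the reference, which changes what a difference is measured from. These were RAB25 in HCT8 (-0.22), CACO2 (-0.28), HCT116 (-0.13), DLD1 (-0.18), COLO205 (-0.0074) and COLO201 (-0.23); AXIN2 (-0.037) and ASCL2 (-0.16) in CACO2; CLDN7 (-0.0044), VIM (0.16), CHAC1 (-0.43) and PHGDH (-0.16) in HCT116; STARD4 (-0.054) and INSIG1 (-0.069) in DLD1; GRB7 (-0.18) and PHGDH (-0.48) in COLO205; MAL2 (-0.11), CDH1 (-1.03), VIM (0.72) and AXL (0.018) in LOVO; and S100A2 (0.37) in HLFA. IDI1 in COLO205 read -0.15 without probe sets ending in _x_at, which replaced its probe set.

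Of 449 cases gene lists lost their call in 56, of which 43 came with the estimated correlation between genes. The intestinal list in T47D reversed in test direction, with a median of -0.0104 against lines of its own spike-in class. Over all lines MYC and CCND1 had rho = -0.179 (p 0.038 by permutation), and rho = 0.068 over lines with 2 or 3 arrays; the cause was not tested. For single genes 62 of 99 counts stayed within 1.5-fold, and 22 of the 37 that moved did so when probe sets were averaged.

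With a replicate block, as if replicate numbers paired the arrays, counts were 3902 (T47D), 2888 (HCT8), 1488 (COLO205 against COLO201), 2024 (SW620 against SW480) and 260 (RKOAS451 against RKO). With only the arrays of COLO205 and COLO201 the block gave 1064 (1017 shared). Signal over background limits all log2 values near 2 to 3.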

Other observations

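The tests of the JIMT1 arrays and the view of other ESR1 probe sets were chosen after the data were seen; the splits and the neighbour correlations were fixed before.

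Replicate 2 of JIMT1 correlated with replicate 1 at 0.8263 over genes that passed the signal limit among all 206 arrays (0.814 over the genes tested), but with the array of BT474, another breast carcinoma line, at 0.9718. KRT5 read 10.55, 1.87 and 1.80 on JIMT1 replicate 1, JIMT1 replicate 2 and BT474, AXL 10.46, 2.07 and 2.00, and VIM 3.78, 10.29 and 9.83. A failed array was argued against by the same 0.9718, and an exchange of labels with BT474 by the correlation of 0.8393 between BT474 and JIMT1 replicate 1. That JIMT1 replicate 2 may hold RNA of BT474, or the BT474 array RNA of JIMT1, stays open, and only 1 array of BT474 was there to compare.

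For each of T47D, HCT8, CACO2, HCT116, DLD1, COLO205, LOVO and COLO201, 1 of 100 drawn splits of the arrays, the real one, called as many genes. The real counts were 3957, 2913, 3589, 2947, 2693, 3708, 3105 and 3441 and the highest other 2293. The other splits mixed arrays of different lines and called a median of 1519 genes, which points to the structure of the samples. A group of 1 line departs further than a mixed group when most genes differ among lines, so these splits do not judge chance on their own. For COLO205 against COLO201 the 10 splits are too few for a share under 0.05; the real one called 1478 genes and the highest other 341. Groups of 2 arrays were not split.

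Differences between neighbouring genes were compared at 10 places apart in genome order, as shared copy number changes might link them. For SW620 against SW480 the correlation was 0.0815, above the highest of the shuffled orders (0.0259), which is consistent with some copy number difference, among other causes of shared regulation. RKOAS451 against RKO gave 0.015 (highest shuffle 0.0317, permutation p 0.054), under the lower limit set beforehand. Only 255 of 13332 genes were called in this pair, so the test had little to detect a shared shift with. It cannot exclude copy number differences there. The value for COLO205 against COLO201, 0.0399 (highest shuffle 0.0345), lay between the limits set and left copy number differences open.

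Mean values of gene lists marked further lines. Melanocyte genes (11 genes, median over lines 3.21) were highest in 624MEL (12.64), 928MEL (12.40), 888MEL (12.17) and G361 (11.87). B lymphocyte genes were high in WSUDLCL2 (10.74), SUDHL4 (10.54), GRANTA519 (10.08), HT (9.77), SC1 (9.36) and DB (9.17), and the next line, H1155, had 4.14. Neuroendocrine genes were highest in H1155 (9.47) and VMRCLCD (8.61), NRF2 target genes in H2122 (12.58), and ERBB2 region genes in HCC1954 (12.78). Class I antigen presentation genes were lowest in COLO704 (4.0) and EVSAT (5.39).

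On another probe set of ESR1, with a lower mean, 11 lines reached 8, among them MCF7 (12.45), T47D (10.94) and SKOV3 (10.71). The rule of the highest mean thus chose a probe set without signal. Of 6443 genes left out of the tests, 87, ESR1 among them, had another probe set over 8 on at least 2 arrays.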
